A study of Noccaea caerulescens with 9 samples.

How the data were processed

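Root RNA of 3 ecotypes of *Noccaea caerulescens*, a metal hyperaccumulator of the cabbage family, was sequenced on the SOLiD platform in 9 libraries. Each of Ganges, La Calamine and Monte Prinzera had 3 libraries, with the replicate numbers 3, 4 and 6, and each library was a pool of 12 root samples, per the labels. The libraries were made from total RNA with a whole-transcriptome kit, per the labels' protocols, and ribosomal and organelle RNA was among what was counted. Plants grew in hydroponic culture, with 10 µM zinc for Ganges and La Calamine and with 2 µM zinc and 10 µM nickel for Monte Prinzera, per the labels' protocols. Any comparison with Monte Prinzera therefore holds ecotype and medium together. Nothing in the labels says whether the pools of an ecotype came from separate cultures, so the p-values measure the spread between these pools, which may in part be technical.

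The deposited values are raw read counts for each annotated exon, coding segment, start codon and stop codon of each transcript. Per the file headers, the authors counted primary alignments with a mapping quality of at least 10, a minimum score of 0 and a score clear zone of 5. The reference was TAIR 9 of *Arabidopsis thaliana*, per the submitters' processing notes, so that reads of one species were placed on the genes of another. The aligner and the counter are not given in the sources used here, and neither is whether the counting used the strand. A gene whose sequence differs more from Arabidopsis loses more reads, several Noccaea copies can fall on 1 Arabidopsis gene, and a deletion or a fast-changing exon lowers a count without any change in expression. Genes that overlap on opposite strands may share counts, and 383 genes overlap another gene on the same strand.

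For each of the 33518 genes in the files, exons with overlapping coordinates were grouped, and the longest exon of a group gave its count. These counts were summed over the groups of a gene, so that an exon listed for several transcripts entered once. Counts of the shorter exons of a group were not used. Gene names were taken from the files, which name 9333 of these genes, and all others are given by their identifier. Summed gene counts ran from 3167382 to 7355120 per library. Mapped reads that the headers report ran from 4069195 to 9292280 per library. At these depths a gene with 0 counts in an ecotype was given a floor of 3 counts over the ecotype, which covers counting error only, because reads without molecular identifiers are not independent molecules.

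Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 19971 genes and removed 13547. Libraries were scaled by TMM, and 1 quasi-likelihood model with ecotype as its factor was fitted to all 9 libraries, so that the 3 ecotypes shared an estimate of the spread. Each pair of ecotypes was compared by a contrast, and an F test over both ecotype coefficients asked for any difference. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold, and rose, fell, higher and lower are relative to the ecotype named second. A gene set apart an ecotype when it was called against both others in the same direction. CPM are counts-per-million values of the TMM-scaled library size, given as mean ± SD over 3 libraries. Log2 fold changes carry standard errors taken from the F statistic.

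The tests, the filter, the alternatives, the lists and the rule for naming genes were chosen before the data were examined. The rule named, in each contrast, the 5 genes with the largest rise and the 5 with the largest fall. These had to be called, reach an absolute log2 fold change of 1 and 10 CPM in the higher ecotype, and have the 3 libraries of one ecotype above the 3 of the other. It also named the 20 called list members with the largest absolute log2 fold change. HMA4, HMA3, MTP1 (ZAT in the files), ZIP4, IRT1, IRT3, NAS2, NAS4, IREG2 (ATIREG2), FER1, PCS1 (CAD1) and MT3 were named in every contrast. For a list, the rule gave as examples up to 4 of its members with the largest absolute log2 fold change. Some passages depart from it and name smaller members, and any other gene named was chosen after its values were seen.

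The 18 lists hold 320 entries and 308 genes, some of them in more than 1 list. They cover ZIP zinc and iron uptake transporters, metal efflux and vacuolar transporters, metal chelation and long-distance transport, iron deficiency response, iron storage, sulfate uptake and assimilation, sulfur deficiency markers, lignin biosynthesis, and Casparian strip and suberin. They also cover glucosinolate metabolism, phosphate starvation response, nitrate and ammonium uptake and assimilation, oxidative and heat stress, and defensins and defence markers. Green shoot tissue, root hair, xylem and phloem, and root meristem and cell division markers stand for cells that a root sample could hold in varying shares. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 54 tests of 18 lists in 3 contrasts. Camera with an estimated correlation and fry were alternatives. Fry asks whether a list changed at all, not whether it changed more than other genes, so its values stand beside those of camera and do not repeat the same test.

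The other alternatives were the size factors of DESeq2, upper-quartile scaling, no filter and a stricter filter of 50 counts in 3 libraries. A DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a fit on the 2 ecotypes compared, and the removal of organelle and ribosomal RNA genes were also run. Each library was left out in turn, and a minimum absolute log2 fold change of 1 was applied. For the number of calls and the named genes of a contrast, only libraries of its 2 ecotypes were left out. Further alternatives chosen after seeing the data were counts of the transcript with most reads, counts without the exon with most reads, the removal of genes that overlap on the same strand, and nuclear protein-coding genes alone.

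The tests were tested on simulated counts drawn from the means and library sizes of the real genes. Of 100 genes changed 2-fold, edgeR recovered 33 for La Calamine minus Ganges (19190 genes), 34 for Monte Prinzera minus Ganges (19341 genes) and 28 for Monte Prinzera minus La Calamine (19577 genes). Of 100 genes changed 4-fold it recovered 87, 76 and 84 in the same order. Far fewer genes were changed here than were called in the real contrasts. The Benjamini-Hochberg threshold depends on the number of calls, so these shares need not hold for the real counts and may be too low. A glucosinolate list raised 1.5-fold was called in both contrasts that held the rise, and 1 of the 52 other list tests was called as well. Genes were drawn independently, so this cannot show how camera behaves when the members of a list are correlated. In the real counts the estimated correlation of this list was 0.22 in Monte Prinzera minus Ganges. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The deposited RPKM values were not used here.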

Results

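Root transcriptomes of 3 *Noccaea caerulescens* ecotypes were compared to find which genes differ between plants with contrasting metal accumulation and tolerance. Ganges and La Calamine come from zinc and lead mine spoil, and Monte Prinzera comes from nickel-rich serpentine soil. Each ecotype had 3 libraries, each a pool of 12 root samples. Summed gene counts per library ran from 4840304 to 5695362 in La Calamine, from 3167382 to 7355120 in Ganges and from 3603922 to 5802466 in Monte Prinzera. Nuclear protein-coding genes held 54.2% ± 1.56 (SD, n = 3) of the counts in Ganges, 50.1% ± 3.43 in La Calamine and 54.0% ± 1.68 in Monte Prinzera. Ribosomal RNA took 35.6 to 41.8% of the counts of a library. Small nucleolar RNAs took 3.64% ± 0.41 in Ganges, 6.04% ± 1.95 in La Calamine and 3.83% ± 0.32 in Monte Prinzera, with 8.24% in La Calamine library 3.

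Libraries grouped by ecotype. The Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.933 to 0.969 between libraries of one ecotype and 0.907 to 0.932 between libraries of different ecotypes. La Calamine libraries were the least alike within an ecotype (0.933 to 0.960) and Monte Prinzera libraries the most alike (0.964 to 0.969). Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.06. The leading principal component held 28.6% of the variance and separated Monte Prinzera, and the next held 25.5% and separated Ganges from La Calamine. La Calamine libraries 6 and 3 lay at opposite ends of the component after these, with scores of 52.3 and −33.3, and it held 12.5%.

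**Figure D1:**
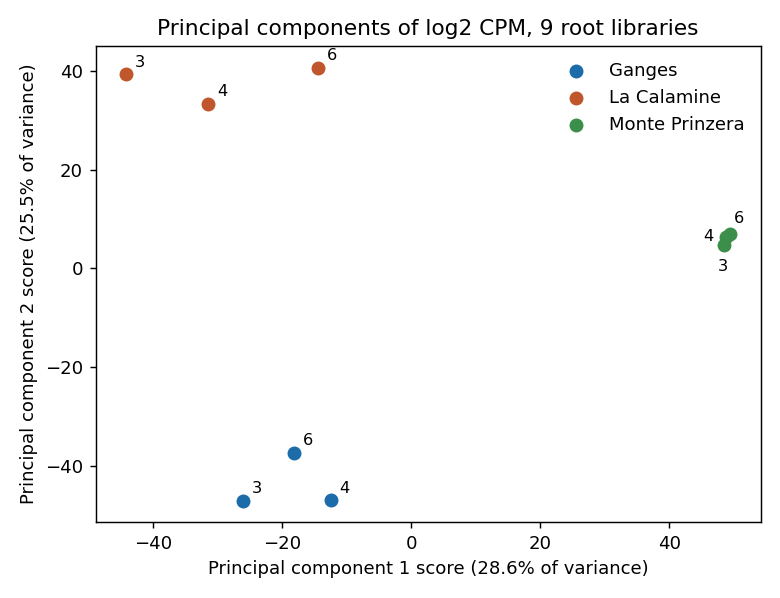
Scores of the 9 root libraries on the leading principal components of log2 CPM, with 28.6% of the variance on the horizontal axis and 25.5% on the vertical axis. Each point is a library, coloured by ecotype and numbered by replicate, and the 3 libraries of each ecotype lie together.

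La Calamine and Ganges grew at the same zinc supply, so their comparison sets the ecotypes side by side in 1 medium. Several metal transporters had much lower counts in La Calamine than in Ganges roots. HMA3 (AT4G30120, chromosome 4, 14730401 to 14733510), a P-type ATPase that moves zinc and cadmium into the vacuole, stood at 148 ± 40.0 CPM (SD, n = 3) in La Calamine and 1443 ± 225 CPM in Ganges. Its log2 fold change was −3.29 ± 0.22 (SE), with an edgeR quasi-likelihood test and Benjamini-Hochberg adjusted p = 2.17e-06. NRAMP1 (AT1G80830), an iron and manganese transporter, stood at 75.7 ± 30.1 CPM against 475 ± 39.4 CPM. HMA4 (AT2G19110, chromosome 2), the ATPase that loads zinc into the xylem, had high counts in both, at 2683 ± 442 and 2588 ± 581 CPM, and its log2 fold change of 0.05 ± 0.17 was smaller than the spread between libraries (edgeR adjusted p = 0.896).

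Of the 13 ZIP zinc and iron uptake transporters tested, 6 fell in La Calamine and the others did not pass, and 6 also fell adjusted over the list alone. ZIP10 fell by 3.33 ± 0.40 on the log2 scale, ZIP9 fell by 2.55 ± 0.38 and IRT1, the main iron transporter of the root surface in Arabidopsis, fell by 2.07 ± 0.38. IRT3 fell by 1.42 ± 0.28, whereas ZIP4 had a log2 fold change of −0.11 ± 0.22. Without its exon with most reads IRT1 was no longer called (edgeR adjusted p = 0.149, with 3.33e-06 to 0.149 over all alternatives). The exons left held 5 and 14 counts in Ganges and 0 and 5 in La Calamine, too few for a fold. Of the 36 metal efflux and vacuolar transporters, 6 fell and 1 rose, and 8 fell and 2 rose adjusted over the list alone. Besides HMA3, NRAMP6 fell by 2.70 ± 0.26, NRAMP1 fell by 2.66 ± 0.26 and ATIREG2 fell by 1.96 ± 0.29, while the vacuolar iron exporter NRAMP3 rose by 1.62 ± 0.23. ZAT (MTP1), a vacuolar zinc transporter, had a log2 fold change of −0.56 ± 0.19 (edgeR adjusted p = 0.0777); it was called without La Calamine library 3 (0.0461) and without its exon with most reads, where 42 counts in Ganges and 1 in La Calamine remained, too few for a fold. Camera placed the ZIP list lower in La Calamine than in Ganges (adjusted p = 0.000109, and adjusted p = 0.199 with an estimated correlation), and the efflux list too (adjusted p = 0.0196, and adjusted p = 0.199 with an estimated correlation). The median log2 fold change of the efflux list was −0.04 and its mean −0.34.

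**Figure D2:**
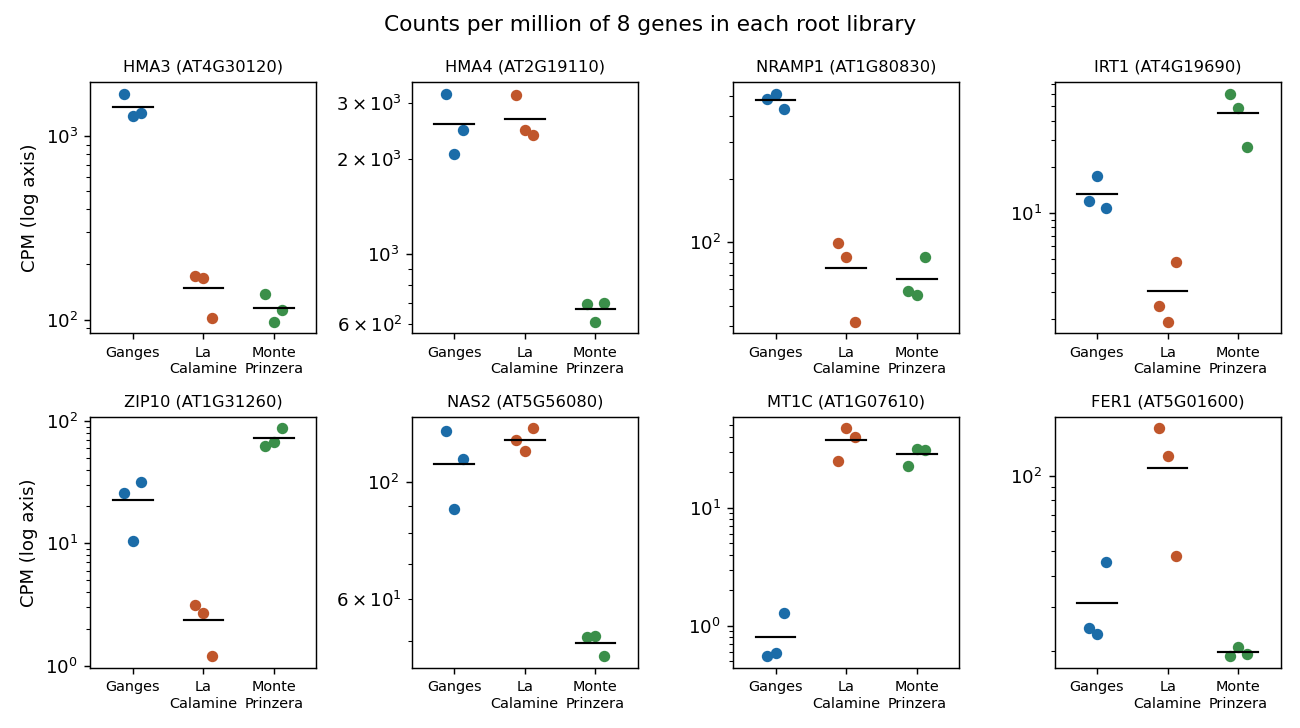
CPM, on log axes, of HMA3, HMA4, NRAMP1, IRT1, ZIP10, NAS2, MT1C and FER1 in the 3 libraries of Ganges, La Calamine and Monte Prinzera. Points are libraries and black lines are means, with HMA3 at a mean of 1443 CPM in Ganges, 148 CPM in La Calamine and 116 CPM in Monte Prinzera.

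Genes of metal chelation went both ways, with 4 of 27 up and 4 down in La Calamine, or 7 up and 4 down adjusted over the list alone (camera adjusted p = 0.0804). The list was called as higher with fry (adjusted p = 0.0484), and with camera without La Calamine library 3 (0.011) or Ganges library 3 (0.0421). The metallothionein MT1C (AT1G07610) rose from 0.809 ± 0.412 CPM in Ganges to 37.2 ± 11.2 CPM in La Calamine, a log2 fold change of 5.52 ± 0.36 that was the largest rise named in this contrast. YSL1, of a family that carries metal nicotianamine complexes, fell by 1.32 ± 0.26, and the citrate exporter FRD3 fell by 0.91 ± 0.20. ZIF1 rose by 1.34, and lost its call in the fit on 2 ecotypes (edgeR adjusted p = 0.0667) and without its exon with most reads (0.0541). The phytochelatin synthase CAD1 (PCS1) rose by 0.64 ± 0.18 (edgeR adjusted p = 0.0422), a call lost without La Calamine library 3 (0.0598), 4 (0.0661) or 6 (0.0775) and without Ganges library 3 (0.057), 4 (0.13) or 6 (0.0692), without a filter on low counts (0.0516) and in the fit on 2 ecotypes (0.0659). The nicotianamine synthases NAS2 (0.15 ± 0.14) and NAS4 (0.54 ± 0.24) and the metallothionein MT3 (0.48 ± 0.20) did not pass, although MT3 was called without La Calamine library 3 (0.048).

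Iron regulators moved in opposite directions. The transcription factors BHLH038 and BHLH039 rose by 2.52 ± 0.50 and 2.43 ± 0.61, the iron sensor EMB2454 (BTS) rose by 1.44 ± 0.18 and CYP82C4, an enzyme of coumarin synthesis, by 2.61 ± 0.53, while FRU (FIT), the master regulator of root iron uptake, fell by 1.67 ± 0.23. Counts of BHLH038 were low, at 73 over the La Calamine libraries and 12 over those of Ganges. BHLH039 had 104 and 17, and its libraries overlapped between the ecotypes. In all, 5 of the 23 tested iron deficiency genes rose and 5 fell, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.717). In iron storage, the ferritin FER1 rose by 1.78 ± 0.34, ATFER4 fell by 1.5 ± 0.28 and ATFER2 fell by 1.3 ± 0.39, so that 1 of 4 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.669). Without the exon with most reads the log2 fold change of FER1 was 0.84 and that of ATFER2 −1.99, both still called. Without La Calamine library 6 and Ganges library 4 in turn, BHLH039 had log2 fold changes of 1.75 and 3.41. It lost its call without La Calamine library 6 (edgeR adjusted p = 0.0728), Ganges library 3 (0.122) or Ganges library 6 (0.0794) and in the fit on 2 ecotypes (0.0609), and CYP82C4 without Ganges library 3 (0.0534). ATFER2 lost its call without La Calamine library 3 (0.104) or 4 (0.156) and without Ganges library 3 (0.108), 4 (0.136) or 6 (0.067). It was also lost with DESeq2 (0.0698), limma-voom (0.0616), upper-quartile scaling (0.0572), the replicate block (0.0588) and the fit on 2 ecotypes (0.074).

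Among the nutrient lists, 3 of 23 sulfate genes rose and 2 fell in La Calamine (7 and 4 adjusted over the list alone), led by the vacuolar sulfate exporter SULTR4;2 at 1.31 ± 0.25 and SULTR3;4 at 1.02 ± 0.18. SULTR4;2 was also the member that rose among 5 sulfur deficiency markers (2 up and 1 down adjusted over the list alone). Of 13 phosphate starvation genes, the transporter APT1 fell by 1.18 ± 0.18 and PHO1 rose by 0.84 ± 0.16 (4 down and 2 up adjusted over the list alone). Of 14 nitrate and ammonium genes, AT4G21680 rose by 1.49 ± 0.33 and WR3 fell by 0.93 ± 0.14 (1 up and 2 down adjusted over the list alone). AT4G21680 lost its call without Ganges library 3 (edgeR adjusted p = 0.0512), and WR3 without its exon with most reads, where its log2 fold change was −0.50 (0.422, with 2.39e-05 to 0.422 over all alternatives). AT4G21680 had a log2 fold change of 2.32 without the exon with most reads. Camera called none of these 4 lists, at adjusted p from 0.419 to 0.860.

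Defence and wall genes gave a mixed picture. The lipoxygenase LOX2, of jasmonate synthesis, fell by 3.06 ± 0.39 (a log2 fold change of −3.74 without La Calamine library 6), while 2 of the 14 tested defence genes rose, the defensin PDF1.2c by 1.83 ± 0.48 and JAZ1 by 0.84 ± 0.22 (3 up and 2 down adjusted over the list alone). In glucosinolate metabolism 3 of 25 genes rose, ESM1 by 2.2 ± 0.46, the myrosinase TGG1 by 1.60 ± 0.47 and CYP83B1 by 1.25 ± 0.17 (6 up and 2 down adjusted over the list alone, camera adjusted p = 0.220). Without La Calamine library 6 the log2 fold changes of ESM1 and TGG1 were 1.22 and 0.50. The calls of both were lost without Ganges library 3 (edgeR adjusted p = 0.0523 and 0.142), and that of TGG1 also without La Calamine library 6 (0.182) and Ganges library 4 (0.072) or 6 (0.133). The TGG1 call was further lost with DESeq2 (0.0939), limma-voom (0.135), the replicate block (0.0706), the stricter filter (0.0581) and the fit on 2 ecotypes (0.103). The glucosinolate list was called as higher with camera without La Calamine library 3 (adjusted p = 0.011) or Ganges library 4 (0.0235). In the fit on 2 ecotypes PDF1.2c (0.0628) and JAZ1 (0.0711) were not called. PDF1.2c lost its call without La Calamine library 4 (0.0773) or Ganges library 3 (0.106), and JAZ1 without La Calamine library 3 (0.102) or 4 (0.085) or Ganges library 3 (0.124) or 4 (0.0538). Of 17 oxidative and heat stress genes 3 fell, of which the catalase CAT3 (AT1G20620) fell by 1.09 ± 0.24 (5 down and 1 up adjusted over the list alone). Camera called neither the defence list (adjusted p = 0.860) nor the stress list (adjusted p = 0.188), and fry called the stress list as lower (adjusted p = 0.0456).

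In the Casparian strip and suberin list no member was called by edgeR over all genes, although 9 of the 20 had an unadjusted p under 0.05 and 7 fell adjusted over the list alone. DESeq2 called 1 of them and limma-voom 3. AT2G36100 had a log2 fold change of −1.28 ± 0.46 and AT3G11550 of −1.22 ± 0.37, both in the family of Casparian strip membrane proteins. Camera placed this list lower in La Calamine than in Ganges (adjusted p = 0.0222, and adjusted p = 0.689 with an estimated correlation), a call lost without La Calamine library 6 (adjusted p = 0.166). Fry did not call the list (adjusted p = 0.0825). Of 21 lignin genes, CYP98A3 fell by 0.42 ± 0.12 (edgeR adjusted p = 0.0446), and no member was called adjusted over the list alone. It lost this call without La Calamine library 3 (0.0717), 4 (0.0633) or 6 (0.126), without Ganges library 3 (0.101), 4 (0.113) or 6 (0.128), and without its exon with most reads, where its log2 fold change was −0.28 (0.136). It was also lost without a filter on low counts (0.087), with the replicate block (0.0661) and in the fit on 2 ecotypes (0.116). Among markers of other cells, the light-harvesting gene LHCB3 rose by 2.05 ± 0.40 as 1 of 10 green shoot genes, at 8.50 ± 2.91 CPM against 1.88 ± 1.17 CPM, and 1 rose adjusted over the list alone. The root hair expansin ATEXPA18 fell by 1.25 ± 0.34 as 1 of 7 root hair genes, a call lost without La Calamine library 3 (0.0671) or 6 (0.0871) and without Ganges library 3 (0.0553), 4 (0.086) or 6 (0.0878), and in the fit on 2 ecotypes (0.0768). It was the 1 root hair gene called adjusted over the list alone too. No marker of xylem and phloem or of the meristem was called by edgeR; at an unadjusted p under 0.05 there were 2 of 7 and 0 of 5, DESeq2 called 0 and 0 and limma-voom 1 and 0. Adjusted over the list alone, 1 xylem and phloem marker rose. Camera called none of the lignin, green shoot, root hair, xylem and phloem, and meristem lists, at adjusted p from 0.0804 to 0.914. It called the green shoot list as higher without La Calamine library 3 (0.011) or Ganges library 4 (0.0235), and the root hair list as lower without La Calamine library 4 (0.0144) or Ganges library 4 (0.0451).

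The largest falls in La Calamine were outside the lists. The mitochondrial reading frame ORF240A stood at 29.7 ± 6.06 CPM against 3284 ± 230 CPM in Ganges, a log2 fold change of −6.79 ± 0.46. AT2G07719 had no count in La Calamine and 10.7 ± 2.54 CPM in Ganges, which makes it at least 54.1-fold lower, with a floor of 3 counts over the ecotype. AT1G14210 fell by 5.80 ± 0.24, AT4G21050 fell by 5.51 ± 0.60 and the gibberellin oxidase GA3OX1 fell by 4.04 ± 0.32. After MT1C, the largest rises were those of the small nucleolar RNA SNOR95 (4.37 ± 0.34), AT3G23880 (4.24 ± 0.42), AT2G35200 (4.07 ± 0.40) and AT1G23120 (3.98 ± 0.46). Without Ganges library 6 SNOR95, AT3G23880 and AT1G23120 were 5.19, 5.19 and 5.89, with another order, and AT1G23120 was 3.36 without Ganges library 3. Without La Calamine library 6 the log2 fold change of AT4G21050 was −6.61. Small nucleolar RNAs as a class rose more often than they fell, with 16 of 57 up and 3 down, a median log2 fold change of 0.60, and 3 of 11 nuclear tRNAs rose. Small nucleolar RNAs held 8.24, 5.35 and 4.53% of the counts in La Calamine libraries 3, 4 and 6. Library 3 also had the lowest share of nuclear protein-coding genes of the 9 (46.4%) and the highest of ribosomal RNA (41.8%), and without it 14 of 58 small nucleolar RNAs rose and 2 fell, at a median of 0.20. Without La Calamine library 6, 25 of 58 rose and 4 fell.

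Over all genes, 1921 of 19971 were called between La Calamine and Ganges by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 935 of them higher and 986 lower in La Calamine. The median absolute log2 fold change of the called genes was 1.11, and 1112 reached an absolute log2 fold change of 1. A fit on these 6 libraries alone called 1196 genes, and without Ganges library 3 the count was 1043.

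Monte Prinzera grew with 2 µM zinc and 10 µM nickel, so its comparison with Ganges asks how a serpentine ecotype on its own medium differs from a mine ecotype on 10 µM zinc. HMA4 and HMA3 had lower counts in Monte Prinzera than in Ganges roots. HMA4 fell from 2588 ± 581 CPM in Ganges to 670 ± 50.7 CPM in Monte Prinzera, a log2 fold change of −1.95 ± 0.18 (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.24e-05). HMA3 stood at 116 ± 20.2 CPM against 1443 ± 225 CPM, with a log2 fold change of −3.64 ± 0.22. NRAMP1 fell by 2.84 ± 0.27, ZAT fell by 1.17 ± 0.19 (without its exon with most reads 42 counts in Ganges and 3 in Monte Prinzera remained, too few for a fold) and AT3G58060, of the cation diffusion facilitator family, fell by 2.65 ± 0.28.

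In the efflux and vacuolar list 7 of 36 members fell and 3 rose in Monte Prinzera, or 10 fell and 5 rose adjusted over the list alone. The risers were AT1G14880 (1.78 ± 0.41), the nickel and iron transporter ATIREG2 (1.06 ± 0.23) and the vacuolar iron exporter NRAMP4 (0.77 ± 0.16, and 1.3 without its exon with most reads). ATIREG2 lost its call without Monte Prinzera library 4 (edgeR adjusted p = 0.0607) and without its exon with most reads (0.0635), and AT1G14880 without Ganges library 3 (0.0664) or Monte Prinzera library 3 (0.0568) or 4 (0.0613). Of 13 ZIP transporters 6 fell and 3 rose, with the same counts adjusted over the list alone. Among the risers, ZIP10 and IRT2 lost their calls without the exon with most reads (edgeR adjusted p = 0.0586 and 0.0843). ZIP9 fell by 2.81 ± 0.38, ZIP6 fell by 2.58 ± 0.28 and ZIP2 fell by 1.67 ± 0.25, while IRT1 rose by 1.8 ± 0.31, from 13.4 ± 3.63 to 45.4 ± 16.9 CPM. ZIP4 fell by 0.97 ± 0.23 and IRT3 fell by 1.17 ± 0.28. Both calls were lost without Ganges library 3 (0.0693 for ZIP4, 0.0692 for IRT3) or 6 (0.0571 and 0.0667) and without Monte Prinzera library 3 (0.0771 and 0.0797) or 4 (0.0584 and 0.0844). Camera called the efflux list (adjusted p = 0.0196, and adjusted p = 0.199 with an estimated correlation) and the ZIP list (adjusted p = 0.0310, and adjusted p = 0.519 with an estimated correlation) as lower in Monte Prinzera than in Ganges. Fry did not call the ZIP list (adjusted p = 0.0696). The ZIP call by camera was lost without Ganges library 6 (0.0674) or Monte Prinzera library 3 (0.107), and the efflux call without Monte Prinzera library 6 (0.0707).

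**Figure D3:**
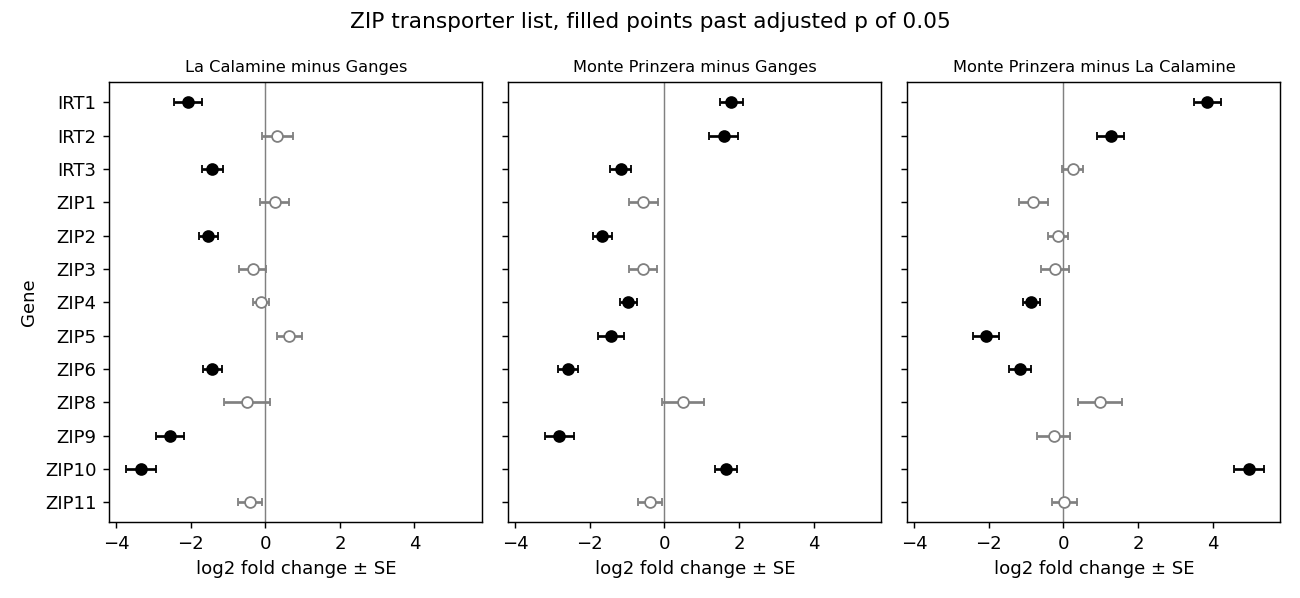
Log2 fold changes of the 13 tested ZIP transporters in the 3 comparisons, with bars of 1 standard error. Filled points passed an adjusted p of 0.05, and ZIP10 and IRT1 were lower in La Calamine and higher in Monte Prinzera than in Ganges; ZIP10 lost its Monte Prinzera call, and IRT1 its La Calamine call, without the exon with most reads.

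Metal chelation genes again went both ways, with 5 of 27 up and 4 down in Monte Prinzera against Ganges, or 8 up and 4 down adjusted over the list alone (camera adjusted p = 0.268). MT1C rose by 5.12 ± 0.37, to 28.3 ± 4.95 CPM. Nicotianamine synthases parted, as NAS3 rose by 2.0 ± 0.37, NAS2 fell by 1.13 ± 0.15 and NAS4 had a log2 fold change of 0.51 ± 0.24. The transporter ATOPT3 rose by 1.57 ± 0.31. MT3 rose by 0.87 ± 0.20, a call lost without Monte Prinzera library 3 (edgeR adjusted p = 0.0602), and CAD1 had a log2 fold change of 0.43 ± 0.18 that did not pass. In the iron deficiency list 5 of 23 rose and 2 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.860). CYP82C4 rose by 2.26 ± 0.54, and lost this call without Ganges library 3 (0.104) or Monte Prinzera library 3 (0.0536) or 4 (0.083). None of the 4 iron storage genes was called by edgeR, 0 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0, and FER1 had a log2 fold change of −0.66 ± 0.36.

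Of the 25 tested glucosinolate genes, 9 rose in Monte Prinzera against Ganges and the others did not pass, and 12 rose and 1 fell adjusted over the list alone. The myrosinases TGG1 and TGG2, which break glucosinolates down, rose by 2.35 ± 0.47 and 2.18 ± 0.45, from 12.1 ± 2.35 to 61.1 ± 11.0 CPM and from 43.2 ± 15.6 to 194.5 ± 36.3 CPM. ESM1 rose by 1.99 ± 0.46 and the biosynthetic enzyme CYP79B3 by 1.16 ± 0.29. Camera called the list as higher in Monte Prinzera than in Ganges (adjusted p = 0.00401, and adjusted p = 0.648 with an estimated correlation), and fry did not (adjusted p = 0.109). ESM1 lost its call without Ganges library 3 (edgeR adjusted p = 0.0783), and CYP79B3 without Ganges library 3 (0.0756) or Monte Prinzera library 3 (0.0837) or 4 (0.0522).

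Of 14 defence markers, 5 rose and 1 fell in Monte Prinzera against Ganges, with the same counts adjusted over the list alone. The defensin-like genes LCR68 and LCR69 rose by 1.88 ± 0.18 and 1.33 ± 0.17, and the pathogenesis-related gene PR1 by 2.61 ± 0.68, whereas LOX2 fell by 3.47 ± 0.41. The glucanase BGL2 rose by 1.46, and lost its call with DESeq2 (adjusted p = 0.0999). With edgeR it was lost without a filter on low counts (adjusted p = 0.0518) and with the replicate block (0.0516). Camera called the defence list as higher (adjusted p = 0.0195, and adjusted p = 0.474 with an estimated correlation). PR1 had a log2 fold change of 3.98 without Ganges library 4 and of 1.99 without library 3. PR1 lost its call without Ganges library 3 (edgeR adjusted p = 0.123) or 6 (0.0888) and without Monte Prinzera library 3 (0.0738) or 4 (0.0901), and with DESeq2 (0.103).

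Camera called none of the other lists in Monte Prinzera against Ganges, at adjusted p from 0.188 to 0.966, and fry called the xylem and phloem list as higher (adjusted p = 0.0131). In sulfate assimilation 1 of 23 rose and 2 fell (2 and 3 adjusted over the list alone), where APS4 fell by 0.96 ± 0.15, and 1 of 5 sulfur deficiency markers rose (1 adjusted over the list alone), the sulfate transporter SULTR1;1 by 1.08 ± 0.29. In nitrate and ammonium uptake 1 of 14 rose and 3 fell (3 and 3 adjusted over the list alone), where NIA1, a nitrate reductase, fell by 1.27 ± 0.22. The fall of WR3 lost its call without its exon with most reads, at a log2 fold change of −0.17 (edgeR adjusted p = 0.803). Of 17 stress genes 3 fell (4 adjusted over the list alone), of which APX2 fell by 1.11 ± 0.21. Without the exon with most reads the falls of ATGSTU19 and CAT2 were −0.16 and −0.50 and were not called (edgeR adjusted p = 0.71 and 0.126). In lignin synthesis ATOMT1 fell by 0.58 ± 0.16 (1 of 21, and 1 adjusted over the list alone), and in the Casparian strip and suberin list GPAT5 fell by 0.99 ± 0.25 (1 of 20, and 1 adjusted over the list alone). The xylem proteases XCP1 (0.75 ± 0.14) and XCP2 (0.73 ± 0.15) rose as 2 of 7 xylem and phloem markers (2 adjusted over the list alone). The light-harvesting gene AT5G01530 fell by 1.68 ± 0.31 as 1 of 10 green shoot genes (1 adjusted over the list alone), and AT1G27740 fell by 1.45 ± 0.40 as 1 of 7 root hair genes (1 adjusted over the list alone). No phosphate or meristem gene was called by edgeR; 4 of 13 and 0 of 5 had an unadjusted p under 0.05, DESeq2 called 0 and 0, and limma-voom 0 and 0. SULTR1;1 lost its call without Ganges library 3 (edgeR adjusted p = 0.143) or 6 (0.084) and without Monte Prinzera library 3 (0.0681), 4 (0.15) or 6 (0.0603). ATOMT1 lost it without Ganges library 3 (0.0721), 4 (0.0658) or 6 (0.0812) and without Monte Prinzera library 3 (0.132), 4 (0.0863) or 6 (0.077), and AT1G27740 without Ganges library 3 (0.143), 4 (0.0517) or 6 (0.0549) and without Monte Prinzera library 3 (0.0594), 4 (0.0895) or 6 (0.105), with DESeq2 (0.0536) and without its exon with most reads (0.136). GPAT5 lost it without Ganges library 3 (0.127), Monte Prinzera library 4 (0.12) or Monte Prinzera library 6 (0.0618) and without its exon with most reads (0.0528).

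Outside the lists, the small nuclear RNA U2.6 rose the most in Monte Prinzera, from 17.9 ± 8.98 to 1185 ± 304 CPM (6.06 ± 0.32 on the log2 scale). AT1G02360 (5.87 ± 0.32), AT5G57790 (5.33 ± 0.54) and the receptor-like protein AtRLP46 (5.07 ± 0.50) followed. ORF240A fell by 6.05 ± 0.45 and AT2G07719 fell by 4.43 ± 0.45, while the log2 fold changes of AT4G21050, AT1G73700 and the arginyl-transferase ATE1 were −4.40 ± 0.53, −3.95 ± 0.36 and −3.85 ± 0.26. Without Monte Prinzera library 3 that of AT4G21050 was −5.73, and without library 4 that of AT5G57790 was 4.70.

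Of the 19971 genes, 2190 were called between Monte Prinzera and Ganges by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1096 higher and 1094 lower in Monte Prinzera, and 1227 reached an absolute log2 fold change of 1. A fit on these 6 libraries alone called 3088 genes. The count was 1078 without Ganges library 3, 1135 without Monte Prinzera library 3, 1095 without library 4 and 1325 without library 6.

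The comparison of Monte Prinzera with La Calamine, ecotypes from serpentine and from mine spoil on different media, gave the most called genes of the 3 contrasts in the fit on all 9 libraries, though not in fits on 6. The transporters IRT1, ZIP10 and ATIREG2 were much higher in Monte Prinzera. IRT1 stood at 45.4 ± 16.9 CPM (SD, n = 3) against 3.04 ± 1.52 CPM in La Calamine, a log2 fold change of 3.87 ± 0.36 (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.84e-05). ZIP10 stood at 72.2 ± 12.8 against 2.35 ± 1.03 CPM (4.97 ± 0.39 on the log2 scale), and ATIREG2 at 21.8 ± 2.08 against 2.70 ± 0.72 CPM (3.02 ± 0.27). HMA4 was lower, at 670 ± 50.7 against 2683 ± 442 CPM, a log2 fold change of −2.0 ± 0.18, whereas HMA3 did not pass (−0.35 ± 0.20, edgeR adjusted p = 0.298) except without La Calamine library 6 (0.0307).

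Of 13 ZIP transporters 3 rose and 3 fell in Monte Prinzera, as they did adjusted over the list alone (camera adjusted p = 0.419). IRT2 rose by 1.27 and lost its call without its exon with most reads, at a log2 fold change of 0.71 (edgeR adjusted p = 0.487). While ZIP10 and IRT1 rose, ZIP5 fell by 2.08 ± 0.35. ZIP4 fell by 0.86 ± 0.23, a call lost without Monte Prinzera library 3 (edgeR adjusted p = 0.108) or 4 (0.0813). IRT3 had a log2 fold change of 0.25 ± 0.28. In the efflux list 5 of 36 rose and 4 fell, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.914), where AT1G14880 rose by 1.73 ± 0.40 and the copper ATPase HMA5 fell by 1.12 ± 0.24. AT1G14880 lost its call without Monte Prinzera library 3 (0.0581) or 4 (0.0592). ZAT had a log2 fold change of −0.61 ± 0.19 (edgeR adjusted p = 0.0555), and was called by DESeq2 (0.043), by edgeR with a stricter filter on low counts (0.0477) and without La Calamine library 6 (0.0141). Of 27 chelation genes 2 fell, as NAS2 fell by 1.28 ± 0.15 and ZIF1 fell by 1.22 ± 0.33, and 2 fell adjusted over the list alone (camera adjusted p = 0.717). ZIF1 lost its call without La Calamine library 4 (0.0532) or 6 (0.0604) and without Monte Prinzera library 3 (0.101), 4 (0.114) or 6 (0.0641), and without its exon with most reads, where its log2 fold change was −0.92 (0.0988). NAS4, CAD1 and MT3 had log2 fold changes of −0.03 ± 0.23, −0.20 ± 0.18 and 0.39 ± 0.20 and did not pass, although MT3 was called without La Calamine library 6 (0.00402).

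In the iron deficiency list 6 of 23 rose and 5 fell in Monte Prinzera, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.695). The fallers included AT3G12900 (−3.21 ± 0.74), BHLH039 (−1.91 ± 0.57) and EMB2454 (−1.64 ± 0.18). In iron storage FER1 fell by 2.44 ± 0.36, from 108 ± 54.5 to 19.8 ± 0.91 CPM, while ATFER4 rose by 1.76 ± 0.28, so that 1 of 4 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.717). Without the exon with most reads the log2 fold change of FER1 was −1.54, still called, and without La Calamine library 6 that of BHLH039 was −1.23. AT3G12900 lost its call without Monte Prinzera library 4 (edgeR adjusted p = 0.0668). BHLH039 lost it without La Calamine library 4 (0.0613) or 6 (0.159) and without Monte Prinzera library 3 (0.0912), 4 (0.149) or 6 (0.122), and with limma-voom (0.0752) or the replicate block (0.0734).

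Nutrient genes differed in both directions. The sulfate transporter SULTR1;1 rose by 2.01 ± 0.31 (2.61 without La Calamine library 4), from 9.03 ± 5.37 to 36.5 ± 7.23 CPM, while SULTR4;2 fell by 1.31 ± 0.25 and APS4 fell by 1.4 ± 0.15, and 4 of 23 sulfate genes rose and 4 fell (4 and 5 adjusted over the list alone). SULTR1;2 rose by 1.42, a call lost with DESeq2 (adjusted p = 0.0569), and SULTR3;4 fell by 1.34. SULTR1;1 and SULTR4;2 were also the riser and the faller among 5 sulfur deficiency markers (1 and 1 adjusted over the list alone). Of 13 phosphate genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), where the phosphate transporter ATPT2 rose by 0.95 ± 0.16 and PHO1 fell by 0.88 ± 0.16. Of 14 nitrate and ammonium genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), where the nitrate transporter NRT1.1 rose by 0.92 ± 0.13 and AT4G21680 fell by 1.58 ± 0.34. Camera called none of these lists, at adjusted p from 0.580 to 0.914.

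Of 14 defence genes 5 rose and 1 fell in Monte Prinzera, among them the defensin-like LCR69, up by 1.84 ± 0.18, and LCR68, up by 1.51 ± 0.17, and the glucanase BGL2 (PR2), up by 1.52 ± 0.43, with the same counts adjusted over the list alone. BGL2 lost its call without La Calamine library 3 (edgeR adjusted p = 0.0883) or 6 (0.109) and without Monte Prinzera library 3 (0.131), 4 (0.0713) or 6 (0.0884). Camera called the list as higher in Monte Prinzera (adjusted p = 0.0310, and adjusted p = 0.474 with an estimated correlation). This call was lost without any 1 of 8 libraries, at 0.0506 without Ganges library 4, 0.0508 without Ganges library 3, 0.0575 without Monte Prinzera library 4, 0.0707 without Ganges library 6, 0.0831 without Monte Prinzera library 6, 0.101 without Monte Prinzera library 3, 0.166 without La Calamine library 6 and 0.212 without La Calamine library 3. Of 17 stress genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), where APX2 fell by 1.76 ± 0.21 and HSP17.6II fell by 1.66 ± 0.49, which lost its call without La Calamine library 3 (0.11) or 4 (0.104) or Monte Prinzera library 3 (0.16) or 4 (0.164), and with limma-voom (0.0514). Of 25 glucosinolate genes 3 rose (5 up and 1 down adjusted over the list alone). Among them CYP79A2 rose by 1.203 and CYP81F2 by 1.13 ± 0.17. CYP79A2 lost its call without its exon with most reads (edgeR adjusted p = 0.388), with upper-quartile scaling (0.0521) and with the stricter filter (0.0533). This call was also lost without La Calamine library 3 (0.138) or 4 (0.147) or Monte Prinzera library 3 (0.104), 4 (0.113) or 6 (0.106). AT3G47960, which also rose, lost its call with upper-quartile scaling (0.0534) and without each of the same libraries in turn (0.0655 to 0.187). Of 21 lignin genes 2 rose and 1 fell (3 and 1 adjusted over the list alone). Camera called none of these 3 lists, at adjusted p from 0.188 to 0.695, but called the glucosinolate list as higher without La Calamine library 6 (0.00115).

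Of 10 green shoot markers 2 fell in Monte Prinzera against La Calamine, AT5G01530 at 2.71 ± 1.27 against 10.0 ± 1.56 CPM (a log2 fold change of −1.82 ± 0.31) and CAB3 with a log2 fold change of −1.52 ± 0.34. The others did not pass, and 3 fell adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.648 with an estimated correlation). Fry did not call the list (adjusted p = 0.0825). The camera call was lost without La Calamine library 6 (0.381) or Monte Prinzera library 4 (0.0575), and that of CAB3 without Monte Prinzera library 3 (edgeR adjusted p = 0.0535). Chloroplast-encoded protein-coding genes went the other way, with 15 of 78 up and 4 down and a median log2 fold change of 0.27. The expansin ATEXPA18 rose by 1.33 ± 0.34 as 1 of 7 root hair genes (1 adjusted over the list alone), a call lost without La Calamine library 3 (0.0509) or Monte Prinzera library 3 (0.0903) or 4 (0.0619). No member of the Casparian strip and suberin, xylem and phloem, or meristem lists was called by edgeR. At an unadjusted p under 0.05 there were 0 of 20, 3 of 7 and 1 of 5, DESeq2 called 0, 0 and 0, and limma-voom 0, 1 and 0. Adjusted over the list alone, 1 xylem and phloem marker rose. Camera called none of the root hair, Casparian strip, xylem and phloem, and meristem lists, at adjusted p from 0.293 to 0.695. Fry called the xylem and phloem list as higher (adjusted p = 0.01), and camera the root hair list without La Calamine library 4 (0.0466).

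The largest rises in Monte Prinzera against La Calamine were those of U2.6 (6.51 ± 0.33 on the log2 scale), AT2G28960 (5.21 ± 0.24), AT1G02360 (5.12 ± 0.29), ZIP10 and AT4G23680 (4.59 ± 0.34, and 2.43 without its exon with most reads). The small nucleolar RNA AT2G43138 fell by 5.42 ± 0.31, SNOR95 fell by 5.05 ± 0.36, AT2G35200 fell by 5.22 ± 0.44, MLP4 fell by 4.71 ± 0.35 and ATE1 fell by 4.29 ± 0.26. Of 57 small nucleolar RNAs 20 fell and 5 rose, or 30 and 5 of 58 without La Calamine library 6, and 18 and 4 of 58 without library 3. Of the 19971 genes, 2448 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1248 higher and 1200 lower in Monte Prinzera, and 1335 reached an absolute log2 fold change of 1. A fit on these 6 libraries alone called 2259 genes. The count fell to 1291 without Monte Prinzera library 3, 1244 without library 4 and 1466 without library 6.

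Over the 3 ecotypes together, 3868 of 19971 genes (19.4%) differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 2495 without Monte Prinzera library 3 and 2397 without library 4. Ganges was set apart by 648 genes, 355 higher and 293 lower than in both others, among them HMA3, NRAMP1, NRAMP6 and AT3G58060 as higher and MT1C as lower. La Calamine was set apart by 720 genes, 390 higher and 330 lower, with SNOR95, FER1 and EMB2454 as higher and IRT1, ZIP10 and ATIREG2 as lower. Monte Prinzera was set apart by 855 genes, 471 higher and 384 lower, with U2.6, AT1G02360, LCR68 and LCR69 as higher and HMA4, NAS2, APX2 and ATE1 as lower. The contrasts of an ecotype share its libraries. In 30 simulations of unchanged groups at most 3, 1 and 1 genes were set apart in this order. These simulations called at most 4 genes in a contrast. They therefore cannot show how many genes the shared libraries would set apart when far more are called. Independent lists would share 54.0 higher and 51.3 lower genes for Ganges, 56.2 and 61.6 for La Calamine and 68.5 and 65.7 for Monte Prinzera. Camera called 9 of the 54 tests of lists over the 3 contrasts, and 11 of 100 splits of the libraries into 3 groups of 3, that by ecotype included, called as many. With 3 libraries an ecotype cannot be split further, so part of the excess may come from the shared libraries. Without Ganges library 3 the counts were 305, 470 and 494, without Monte Prinzera library 3 they were 407, 442 and 417, and without Monte Prinzera library 4 they were 382, 414 and 400. Without Monte Prinzera library 6 La Calamine was set apart by 474 genes and Monte Prinzera by 480.

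Counts of single exons showed whether a difference ran along a gene. HMA3 was higher in Ganges than in each other ecotype in all 9 of its exons, and NRAMP1 in all 11. HMA4 was lower in Monte Prinzera than in La Calamine in all 9 exons with at least 20 counts, and lower than in Ganges in 8 of these 9. Exon 3 of HMA4 (chromosome 2, 8280926 to 8281183, TAIR 9), chosen after its values were seen, was the exception, with 2.80 ± 2.46 CPM in Ganges, 51.6 ± 6.12 in La Calamine and 5.75 ± 1.61 in Monte Prinzera.

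**Figure D4:**
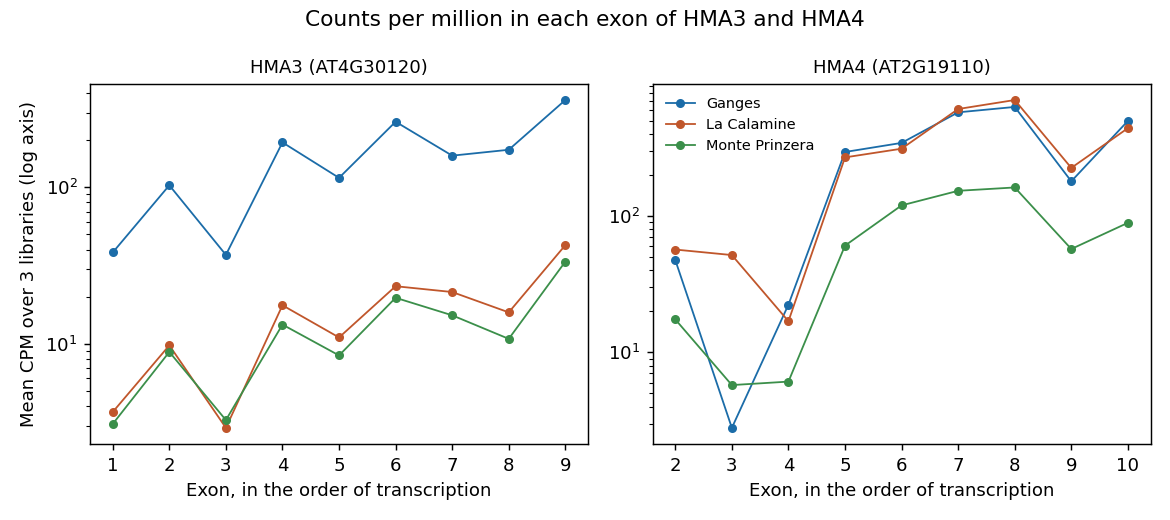
Mean CPM over 3 libraries, on log axes, in each exon of HMA3 and HMA4, with exons numbered in the order of transcription. Exons under 20 counts in every ecotype are left out, and exon 3 of HMA4 stands at 2.80 CPM in Ganges against 51.6 CPM in La Calamine, while the other exons of these ecotypes lie close together.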

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

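The tests of single exons and of the share of mitochondrial RNA were chosen after their results were seen, as was ORF122C, and the others were fixed before.

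Some mapped reads that the headers report were in no gene count, 22.28% ± 1.5 (SD, n = 3) in Ganges, 24.8% ± 0.84 in La Calamine and 24.5% ± 0.29 in Monte Prinzera. These shares are the mapped reads less the summed gene counts. Such reads may lie outside exons, or only in overlapping exons whose counts were not used. They may also have been removed by the filters on mapping quality, primary alignments and score, and none of this was tested. No control library was measured, and these reads were not analysed here.

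The first pattern is the large changes of members of the lists, with 111 calls of 68 list genes at an absolute log2 fold change of at least 1. If the exon with most reads over all libraries were the cause, by mapping better in one ecotype, most calls would shrink without it. Of 92 calls testable without it, 89 (96.74%) kept their direction and at least 50% of their log2 fold change, and 82 were still called. This argues against the exon with most reads as the cause for these 92 as a set. A call made by another exon would be kept too, so the test cannot decide on other single exons. The 89 include ZAT in Monte Prinzera minus Ganges (−1.17 to −3.65) and IRT1 in La Calamine minus Ganges, with too few reads left for a fold. The 3 exceptions were FER1 in La Calamine minus Ganges (1.78 to 0.84), ZIP10 in Monte Prinzera minus Ganges (1.65 to 0.82) and CYP79A2 in Monte Prinzera minus La Calamine (1.203 to 0.58). For the other 19 calls a single exon cannot be told apart from other causes, as 6 were of single-exon genes and 13 had too few reads left (of MT1C, ATEXPA18, BHLH038, BHLH039, PDF1.2c, LCR68, BGL2 and MTPA1), and with these as not kept the share was 80.18% of all 111. Divergence of a whole gene from the Arabidopsis sequence, a difference in copy number and a difference in expression between ecotypes all stay open and were not tested, and in contrasts with Monte Prinzera the medium cannot be told apart from the ecotype.

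The next pattern is the far lower count of ORF240A (ATMG00690) and AT2G07719 in La Calamine and Monte Prinzera than in Ganges. More mitochondrial RNA in Ganges would lower all mitochondrial genes alike, yet the other 53 mitochondrial protein-coding genes had a median log2 fold change of 0.04 in La Calamine and −0.01546 in Monte Prinzera, against −6.79 and −6.05 for ORF240A. Reads of ORF240A counted instead at the copy of mitochondrial DNA on chromosome 2 (3227034 to 3593227, 148 genes, with bounds from general knowledge and not from a file) would raise that copy, yet its summed CPM changed by −176.4 in La Calamine and was lower still in Monte Prinzera; AT2G07719 is itself a gene of this copy, so this test is of ORF240A alone. ORF122C (ATMG00680) had 70 counts in Ganges, 2 in Monte Prinzera and 0 in La Calamine, at least 22.8-fold lower there, with a floor of 3 counts over the ecotype. A difference in mitochondrial sequence between ecotypes may remain as an explanation, as may reads lost at the mapping quality limit, and neither was tested.

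The last pattern is that adjacent genes over 1 kb apart were called in the same direction more often than in shuffled calls. Between La Calamine and Ganges there were 100 such pairs against a shuffled mean of 52.0, between Monte Prinzera and Ganges 114 against 68.1, and between Monte Prinzera and La Calamine 127 against 84.9, each at a one-sided permutation p of 0.001, the smallest that 1000 shuffles can give. Pairs in opposite directions numbered 49, 64 and 85, near their shuffled means of 51.9, 68.2 and 84.1. Genes 10 places apart, taken without a minimum gap, gave 104, 124 and 145 pairs against 90.7, 118 and 146 (one-sided permutation p = 0.0819, 0.308 and 0.573). No excess was thus called at this distance. Distances in between were not tried, so the range of the clustering stays open. Reads shared between neighbouring copies of a gene family cannot be told apart from other local causes, because both would fade over this distance.

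Other groupings of the libraries were set against the grouping by ecotype. For a pair of ecotypes the 6 libraries make 10 splits, too few for a share under 0.05, and only 1 split, the real one, gave as many genes, with 1196, 3088 and 2259 calls for La Calamine minus Ganges, Monte Prinzera minus Ganges and Monte Prinzera minus La Calamine and 0 in the highest other split by edgeR. Over 100 of the 280 splits of all 9 libraries into 3 groups, the real one gave 3868 genes that differed between any ecotypes. The highest other split gave 696, so an arbitrary grouping can be excluded for this number. The numbers of genes that set Ganges, La Calamine and Monte Prinzera apart, 648, 720 and 855, were also above the 338 of the highest other split. These splits exchange libraries of all 3 ecotypes, so they speak only against a grouping in which no ecotype differs. They cannot exclude an arbitrary grouping for each ecotype, as a pair of ecotypes has only the 10 splits. The other splits mix ecotypes, which adds their differences to the spread within groups. The ranking therefore does not exclude chance for single genes, and it cannot tell ecotype from culture or pool. An arbitrary grouping cannot be excluded for the 9 list tests that camera called, because 11 of the 100 splits gave as many and the highest other gave 12.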

How the results depend on the processing

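Counts of the transcript with most reads, counts without the exon with most reads, the removal of genes overlapping on the same strand, nuclear protein-coding genes alone and the small RNA classes with each library left out were chosen after seeing the data. Of the 198 calls of named and list genes, 113 were kept under every alternative in which the gene was tested. Of the others, 85 were lost under some, and 0 turned direction. The minimum absolute log2 fold change was not among these alternatives. Leaving out a library of the ecotype outside the contrast was not among them either. An alternative that left a gene untested was not counted against its call. Of 9 list calls by camera none was kept under all alternatives run for the lists, and with an estimated correlation 0 were called.

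A minimum absolute log2 fold change of 1 left 1112 calls for La Calamine minus Ganges, 1227 for Monte Prinzera minus Ganges and 1335 for Monte Prinzera minus La Calamine, and 359, 366 and 439 genes that set Ganges, La Calamine and Monte Prinzera apart. Fits on the 6 libraries of a pair of ecotypes called 1196 genes for La Calamine minus Ganges, 3088 for Monte Prinzera minus Ganges and 2259 for Monte Prinzera minus La Calamine, so the count fell in 2 contrasts and rose in the one without La Calamine. With each library of the 2 ecotypes compared left out in turn, the 3 contrasts ranged from 1043 to 2128, from 1078 to 1772 and from 1244 to 3043 calls. Libraries of the ecotype outside a contrast share in the estimate of the spread, but were not left out for these ranges. With each of all 9 libraries left out in turn, any difference ranged from 2397 to 4731. The genes that set an ecotype apart then ranged from 305 to 739 (Ganges), 414 to 948 (La Calamine) and 400 to 1201 (Monte Prinzera). The highest counts of both contrasts with La Calamine came without La Calamine library 6, and the cause of this was not tested. A pair of libraries left in an ecotype shares its spread with the other ecotypes in that fit.

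DESeq2 called 1855, 2057 and 2286 genes in the 3 contrasts and limma-voom 1921, 2249 and 2393. The stricter filter called 1500, 1746 and 1993 of 10476 genes. Without the exon with most reads 1404, 1632 and 1673 of 12531 genes were called. In simulated counts at these depths, with 3 libraries per ecotype, edgeR recovered 33, 34 and 28 of 100 genes changed 2-fold. Far fewer genes were changed there than were called in the real contrasts, so the real share recovered may be higher.

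The replicate numbers are shared between ecotypes. Deviations of libraries with the same number correlated at −0.0842 to 0.185, and those of libraries with different numbers at −0.1915 to 0.1557. Of the 9 pairs with the same number 1 was above 0.1, so the numbers were not taken to pair the libraries. Of the 9 libraries, 3 correlated best with their own number in both other ecotypes, a hint from the data only that was not set against chance. With the replicate block the contrasts called 1764, 2001 and 2300 genes, 3479 differed in any way, 594, 665 and 776 set an ecotype apart, and 9 list tests were called.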

Other observations

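The small RNA classes and exon 3 of HMA4 described here were chosen after their values were seen.

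Of 12 small nuclear RNAs of the spliceosome, 6 rose and 1 fell in Monte Prinzera against Ganges and 3 rose and 1 fell against La Calamine, with median log2 fold changes of 0.75 and 0.71. Against Ganges, 2 rose without Ganges library 3 or 4 and without Monte Prinzera library 3, 4 or 6. Against La Calamine, 5 rose without La Calamine library 6, and 2 without La Calamine library 3 or Monte Prinzera library 3, 4 or 6. U12 stood at 6.85 ± 2.89 CPM (SD, n = 3) in Ganges, 16.4 ± 6.58 in La Calamine and 31.6 ± 7.76 in Monte Prinzera, with a log2 fold change of 2.15 ± 0.33 in Monte Prinzera against Ganges (edgeR adjusted p = 0.00106). Small nucleolar RNAs, which guide the modification of ribosomal RNA, had a median log2 fold change of 0.60 in La Calamine against Ganges and −0.62 in Monte Prinzera against La Calamine, which were 0.20 and −0.34 without La Calamine library 3. Between Monte Prinzera and Ganges 5 of 57 rose and 7 fell.

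Exon 3 of HMA4 held 0.109% ± 0.101 (SD, n = 3) of the counts of the gene in Ganges, 1.93% ± 0.0933 in La Calamine and 0.852% ± 0.190 in Monte Prinzera. The cause was not tested. Of the genes that passed edgeR's filter, 3 had no count in La Calamine, 0 in Ganges and 0 in Monte Prinzera, and 1 of these 3 reached 10 CPM in another ecotype.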
